A study of Oryza sativa with 12 samples.

How the data were processed

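Gene expression was measured in panicles of 2 rice (Oryza sativa) cultivars, IR64 and Nagina 22 (N22), with 12 Affymetrix rice arrays and 1 array per sample. The arrays fall into 4 groups of 3: IR64 control, IR64 heat, N22 control and N22 heat. Per the labels, IR64 is susceptible to heat and N22 is tolerant, and planting was staggered so that both flowered together. Plants under heat stood for 8 days in a facility kept 5 °C warmer than the air outside, starting at booting, and control plants grew in an open field beside it. Heat treatment and growing site were thus changed together in every comparison of heat with control. How many plants were pooled per sample is not given in the sources used here.

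The authors deposited a single table of log2 expression values for 57381 probe sets, made with GCRMA, a method that subtracts background by probe sequence, normalises across arrays and summarises the probes of each set. Its software version and settings are not given in the sources used here. The values lie between 2.29 and 15.8, and 38.6% of them sit at the floor of 2.29. The array medians lie between 2.34 and 2.37. No detection calls came with the table, and raw scanner files were not used here. All columns of the table were used.

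The 123 control probe sets (names that begin with AFFX) were left out of all tests. A probe set was kept where its value exceeded the median of the whole table, 2.35, on at least 3 of the 12 arrays, which left 29801 for testing. A linear model of the 4 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with eBayes at its default settings (8 residual and 1.79 prior degrees of freedom). The fit tested 5 contrasts: heat minus control in IR64, heat minus control in N22, N22 minus IR64 in control, N22 minus IR64 in heat, and the difference of the heat effects (N22 minus IR64). A probe set counts as called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, and calls of at least 2-fold are counted beside this. Changes are log2 differences of group means with the standard error (SE) of the fit, and group means carry the standard deviation (SD) of 3 arrays. Nothing in the labels says that replicates came from separate plants, so the p-values measure the spread between these samples alone, which may be technical. With 3 arrays per group, their number limits the precision.

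A level of 4.20, the highest value of 64 reporter probe sets on the array that match no rice gene, served as background. Where all 3 arrays of a group lay at or under it, the fold is given as a lower bound, "at least N-fold", from the mean of the brighter group to this level. Where both groups lay there, no fold is given. This background level was chosen after the data were examined.

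Probe sets were paired with genes through the annotation of the array and named with the gene table of the assembly ASM3414082v1. In all, 22436 probe sets paired with exactly 1 gene, 95 with several and 34850 with none. All 17905 genes on the array were found in the table, but 2457 of them had an informative name, of which 2276 were tested. No coordinates are given, since the build behind the array annotation was not stated. Gene lists were tested with camera in limma on 1 probe set per gene, the brightest over the 12 arrays, which gave 16069 genes. The preset correlation between genes was 0.01, and p-values were adjusted over 52 lists and 5 contrasts, 260 tests. The same test was run with a correlation estimated for each list. The titles of 43 lists were set before the data were examined, and 16 lists were added after the gene names had been read. Members of all lists were chosen by gene symbol after the gene table had been read and before any gene's values were examined, since the table held symbols and no descriptions. A list needed 5 kept genes, which left out 7 lists: HSP70 (2 genes), HSP90 (3), chaperonins (1), class III peroxidases (2), ethylene synthesis (4), pectin-modifying enzymes (2) and late pollen genes (3).

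The genes named were chosen by a rule written before the data were examined. It takes, per contrast, the 10 largest rises and the 10 largest falls (8 and 8 for the cultivar contrasts and the difference) among called probe sets with all 3 arrays of a group above all 3 of the other. It adds up to 4 members with the smallest adjusted p of each list described, and every gene of a fixed list of 20 heat sentinel genes. The rule asked for an informative description. The table had none, so an informative name was required instead. Probe sets that can match several transcripts are named as shared.

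RNA quality was read from control probe sets for the 3' end, middle and 5' end of GAPDH, ubiquitin, cyclophilin and actin, compared by two-sided exact permutation tests whose smallest possible p for 3 against 3 arrays is 0.1. The comparison was void for the 5' end of actin and of cyclophilin, which lay at background on 12 and on 10 of the 12 arrays. The alternatives planned before the data were examined comprised other filters, quantile normalization, centring of each array on its median, other moderation, array weights, fits on the compared groups alone, the replicate number as a block, the mean of a gene's probe sets in place of the brightest for the lists, and leaving out each array in turn. A filter at the background level and raising every value to that level were chosen after the data were seen. The analysis was tested on simulated data for the heat effect in N22 with 29801 probe sets, of which 200 were changed. It recovered 94% of those changed 2-fold and 100% of those changed 4-fold, but 18 of its 212 calls were false, 8.49% where 5% is nominal. It made 0 calls where none had been changed. All changed probe sets were drawn from those with a mean above 6.15, the 75th percentile of the table. The simulation thus does not show recovery for dimmer probe sets or those near the floor. It also changed far fewer probe sets than the 15412 called for heat in N22. Figures were drawn with Python 3.11.15, matplotlib 3.10.9 and numpy 2.4.6, and R used data.table (version 1.17.8) and statmod (version 1.5.0).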

Results

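Panicles of IR64, a cultivar the labels call heat-susceptible, and of N22, which they call heat-tolerant, were compared after 8 days at 5 °C above ambient and in open-field controls, with 3 arrays per group. Between 33.2% and 34.4% of the probe sets on each array lay above the background level of 4.20. The series asks which genes respond to heat in N22 in particular, so each heat effect is given first and then the test of their difference.

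In IR64 panicles, the largest falls under heat among the 2276 tested genes with an informative name included genes of lignin and secondary cell wall synthesis. Genes without such a name were not ranked. 4CL5 (LOC4345717), a 4-coumarate:CoA ligase of the phenylpropanoid pathway, went from a mean of 11.07 ± 0.06 (SD, n = 3) to background, at least 117-fold lower. Its relative 4CL3 (LOC4328485) fell by 5.87 ± 0.09 on the log2 scale (SE, 3 arrays per group), and PAL06 (LOC4330040), a phenylalanine ammonia-lyase, fell by 5.98 ± 0.21. The cellulose synthases of secondary walls moved with them: CESA4 (LOC4324625) fell by 5.95 ± 0.09, CESA7 (LOC4348853) fell by 5.96 ± 0.20 and CESA9 (LOC4347093) was at least 20.8-fold lower. Sucrose synthase SUS1 (LOC4333062) fell by 6.26 ± 0.08 and BC1 (LOC4333114), which is needed for stiff culms, fell by 5.65 ± 0.13.

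Other large falls in IR64 were those of the beta-expansin EXPB9 (LOC4349301), which fell by 5.33 ± 0.20, and NifU1 (LOC4351651, shared probe set), at least 12.7-fold lower. Among genes that the naming rule allows, the largest rise was that of GLU5 (LOC4324643), 5.24 ± 0.17. GLT2 (LOC4339561) rose by 3.94 ± 0.14, the small heat shock protein gene HSP16.9A (LOC4325697) by 3.51 ± 0.07, the homeobox gene HOX12 (LOC4331956) by 3.37 ± 0.19 and the heat stress transcription factor gene HSFC1B (LOC4324158) by 3.06 ± 0.08. From background in the controls, hox14 (LOC4343726) rose at least 8.31-fold, the glutaredoxin GRXC1 (LOC4325734) at least 7.31-fold, the laccase LAC7 (LOC4324802, shared probe set) at least 4.81-fold, MADS13 (LOC4351753, shared probe set) at least 2.44-fold and BHLH172 (LOC4340551) at least 2.31-fold.

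By list, 13 of the 19 phenylpropanoid enzyme genes fell in IR64 and 0 rose, with 6 not called and 13 called when adjusted over the list alone. Their median was -1.08, with HCT1 at -4.03 ± 0.08 and CAD2 (shared probe set) at -3.75 ± 0.07. The list was called at adjusted p = 0.000317 with the preset correlation, and had adjusted p = 0.110 with an estimated correlation. Of 44 genes of cell wall synthesis, 27 fell, 7 rose and 10 were not called (median -0.52, adjusted p = 0.00263, and adjusted p = 0.126 with an estimated correlation). XOAT11 (shared probe set) fell by 3.93 ± 0.10 and CSLF2 at least 2.59-fold. Of 9 beta-expansin genes, whose products loosen cell walls, 7 fell, 0 rose and 2 were not called (median -1.66, or -1.01 with values raised to background, adjusted p = 0.00385). Its adjusted p = 0.126 with an estimated correlation. EXPB10 was at least 5.33-fold lower and EXPB3 (shared probe set) fell by 2.64 ± 0.15. All 6 glutathione S-transferase genes fell, also when adjusted over the list alone (6 of 6; median -2.75, adjusted p = 0.00111, and adjusted p = 0.126 with an estimated correlation). GST1 (shared probe set) fell by 4.53 ± 0.11 and GSTU6 by 3.03 ± 0.10.

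Protein folding, protein turnover and respiration genes were lower in heated IR64 panicles by smaller amounts. Of 28 genes of protein folding in the endoplasmic reticulum (ER), 20 fell, 2 rose and 6 were not called, with 23 called when adjusted over the list alone. Their median was -0.50, with the calreticulin gene CRO1 (shared probe set) at -2.54 ± 0.07 and ERDJ3B at -1.68 ± 0.05 (adjusted p = 0.000491, and adjusted p = 0.126 with an estimated correlation). Of 19 proteasome subunit genes, 18 fell, as they did when adjusted over the list alone, 0 rose and 1 was not called (median -0.69, adjusted p = 4.05e-05, and adjusted p = 0.126 with an estimated correlation). OsPBB1 changed by -1.20 ± 0.07 and PAE1 by -1.06 ± 0.08. Of 23 genes of mitochondrial respiration, 21 fell, 0 rose and 2 were not called, with 21 called when adjusted over the list alone (median -0.87, adjusted p = 1.4e-05). PDHE1-A, a pyruvate dehydrogenase subunit, fell by 1.64 ± 0.06 and SDH5, of succinate dehydrogenase, by 0.99 ± 0.05, and the list had adjusted p = 0.110 with an estimated correlation. Of 80 calcium signalling genes, 47 fell, 11 rose and 22 were not called, with 58 called when adjusted over the list alone (median -0.43, adjusted p = 0.00213, and adjusted p = 0.126 with an estimated correlation). CBL6 fell by 1.08 ± 0.04 and CIPK29 was at least 2.97-fold lower.

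The classical heat shock genes of IR64 gave a mixed picture after these 8 days. Among 19 small heat shock protein genes, 3 rose, 10 fell and 6 were not called, with 13 called when adjusted over the list alone, and the list itself was not called (median -0.60, adjusted p = 0.0930). Of 19 heat sentinel genes with a kept probe set, 3 rose, 10 fell and 6 were not called, with 13 called when adjusted over the list alone. The median was -0.90 (adjusted p = 0.0382, and adjusted p = 0.245 with an estimated correlation). HSP81-1, an HSP90 gene, changed by -2.23 ± 0.04, the heat stress transcription factor gene HSFB2C by -3.10 ± 0.11, the ER chaperone gene BIP1 by -1.86 ± 0.10 and the disaggregase gene HSP101 by -0.90 ± 0.08, while HSP81-2 rose by 0.81 ± 0.05. Without IR64 heat replicate 2 the sentinel list was no longer called (adjusted p = 0.0554). The lists for the clock (5 up, 0 down, 2 not called, and 5 called when adjusted over the list alone) and for homeobox genes (19 up, 6 down, 12 not called) rose, with medians of 0.69 and 0.43 and adjusted p = 0.0250 and 0.0382. With an estimated correlation the adjusted p values were 0.245 and 0.294. The clock gene PCL1 rose by 2.40 ± 0.05, and HOX1A by 1.02 ± 0.05. Metal homeostasis genes fell (23 down, 7 up, 17 not called, median -0.27), among them MT-2 (shared probe set) by 1.24 ± 0.04, with another of its probe sets called the opposite way, and ZIP3 by 2.24 ± 0.09. The adjusted p = 0.0456, and adjusted p = 0.313 with an estimated correlation. Some alternatives end the calls of the clock, homeobox and metal lists, among them the mean of a gene's probe sets for the clock (adjusted p = 0.0662), no filter for the homeobox genes (median 0.11, adjusted p = 0.0555) and for the metal genes (adjusted p = 0.0604). The homeobox call also ended with quantile normalization (adjusted p = 0.0627) and median centring (adjusted p = 0.0600), and the metal call when any of 3 arrays was left out (adjusted p = 0.0510, 0.0628 and 0.0549).

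**Figure D1:**
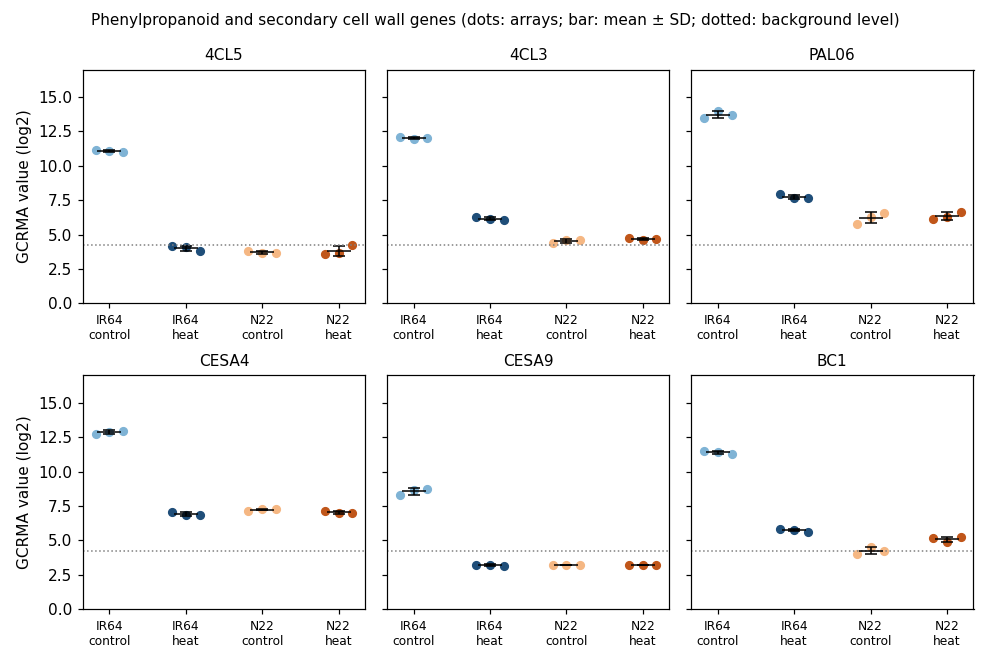
GCRMA values (log2, vertical axis) of 6 phenylpropanoid and secondary wall genes in the 4 groups, with dots for arrays, bars for mean ± SD (n = 3) and a dotted line at the background level of 4.20. 4CL5 had a mean of 11.07 in IR64 control, against 3.70 in N22 control and 3.81 in N22 heat.

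In total, limma called 15427 of 29801 probe sets for heat in IR64, 7217 up and 8210 down, of which 5171 moved at least 2-fold (1917 up, 3254 down). Centring each array on its median moved the median of all probe sets by 0.11 and turned the split to 9129 up and 6938 down, while falls stayed ahead at 2-fold or more (2393 up, 2833 down, and 2370 and 2853 with quantile normalization). The RNA of IR64 control gave a smaller 3' excess than that of the other groups: the 3' minus 5' difference of GAPDH was 4.79 ± 0.18 in IR64 control and 7.93 ± 0.16 in IR64 heat (SD, n = 3; exact permutation p = 0.1, the smallest possible). For ubiquitin it was 1.45 ± 0.03 and 2.15 ± 0.01. This shift moves with every gene group described for heat in IR64. The spike-in probe sets also rose with heat in IR64, by 0.82 (added at hybridisation) and 1.51 (added at labelling). Both exceed the median rises of the clock and homeobox lists.

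In N22 panicles, small heat shock protein genes, whose products bind unfolding proteins, rose together under heat. HSP21.9 (LOC4350180) lay at background in N22 control and was at least 892-fold higher in heat (3 arrays per group). HSP16.9B (LOC4325698) rose by 6.53 ± 0.19 (SE, 3 arrays per group), HSP23.2 (LOC4335956) by 6.46 ± 0.19, HSP17.4 (LOC4332360) by 5.00 ± 0.15 and HSP18.1 (LOC4332361) by 4.89 ± 0.08. Of the 19 genes of the list, 18 rose, 1 fell and 0 were not called, and 19 were called when adjusted over the list alone. Their median was 2.22, or 2.06 with values raised to background (adjusted p = 1.4e-07, and adjusted p = 0.110 with an estimated correlation).

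**Figure D2:**
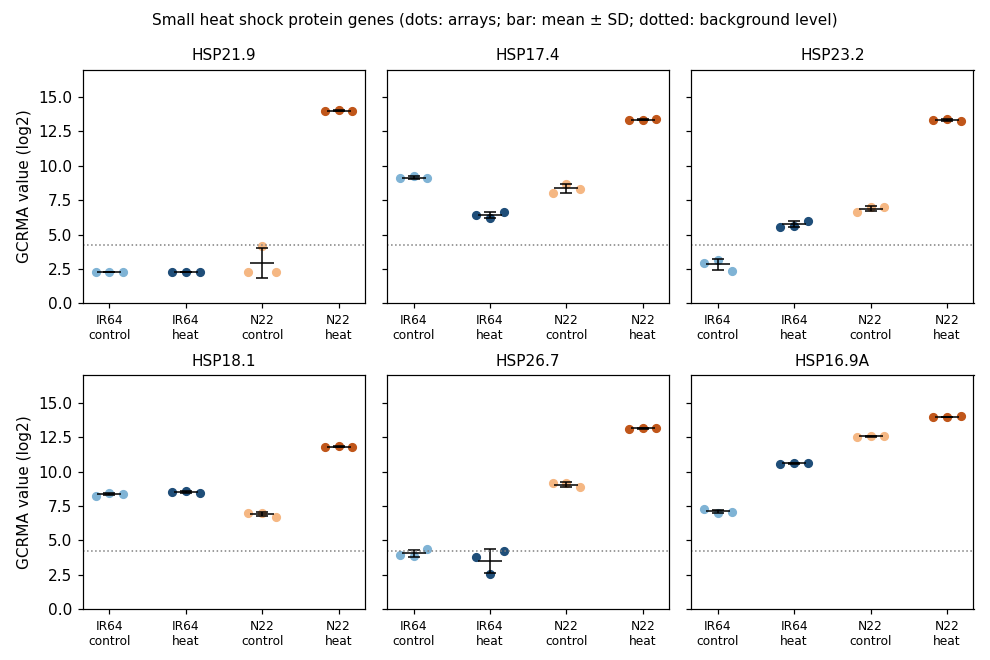
GCRMA values (log2, vertical axis) of 6 small heat shock protein genes in the 4 groups, with dots for arrays, bars for mean ± SD (n = 3) and a dotted line at the background level of 4.20. HSP17.4 had a mean of 13.36 in N22 heat and of 9.14, 6.44 and 8.36 in IR64 control, IR64 heat and N22 control.

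Photosynthesis genes rose in heated N22 panicles as well. Of 37 genes, 26 rose, 4 fell and 7 were not called, with 31 called when adjusted over the list alone (median 1.62, adjusted p = 2.1e-07, and adjusted p = 0.156 with an estimated correlation). OEE3 of photosystem II (shared probe set) rose by 3.57 ± 0.07, the Rubisco small subunit gene RBCS by 3.09 ± 0.07 on a probe set that may cross-hybridise, the plastocyanin gene PETE (shared probe set) by 2.82 ± 0.07, and GS2, the plastid glutamine synthetase, by 3.54 ± 0.08.

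Genes of diterpenoid phytoalexins, the antimicrobial compounds of rice, and of other defence proteins rose too. The phytoalexin and defence lists were lower in N22 control than in IR64 control (below), and both comparisons share the N22 control arrays. A response to heat was not told apart from a changed share of tissues. Of 13 phytoalexin genes, 10 rose, 0 fell and 3 were not called (median 3.16, or 2.14 with values raised to background, adjusted p = 5.8e-05, and adjusted p = 0.213 with an estimated correlation). CYP701A8 (LOC4341343) rose by 4.61 ± 0.14, CYP71Z7 by 3.34 ± 0.12, and the synthase gene KSL7 at least 9.74-fold. Of 29 defence protein genes, 17 rose, 4 fell and 8 were not called, with 22 called when adjusted over the list alone (median 0.63, adjusted p = 0.00519, and adjusted p = 0.326 with an estimated correlation). The chitinase genes LOC4336265 and LOC4348631 rose by 2.64 ± 0.08 and 3.03 ± 0.13. Of 30 jasmonate genes, 15 rose, 4 fell and 11 were not called, with 19 called when adjusted over the list alone (median 0.31, or 0.20 with values raised to background, adjusted p = 0.0381, and adjusted p = 0.245 with an estimated correlation). COI1B, of the jasmonate receptor family, rose by 1.64 ± 0.05 and JAZ8 by 1.03 ± 0.09. Without N22 control replicate 3 or N22 heat replicate 3 the jasmonate list was no longer called (adjusted p = 0.0505 and 0.0557).

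**Figure D3:**
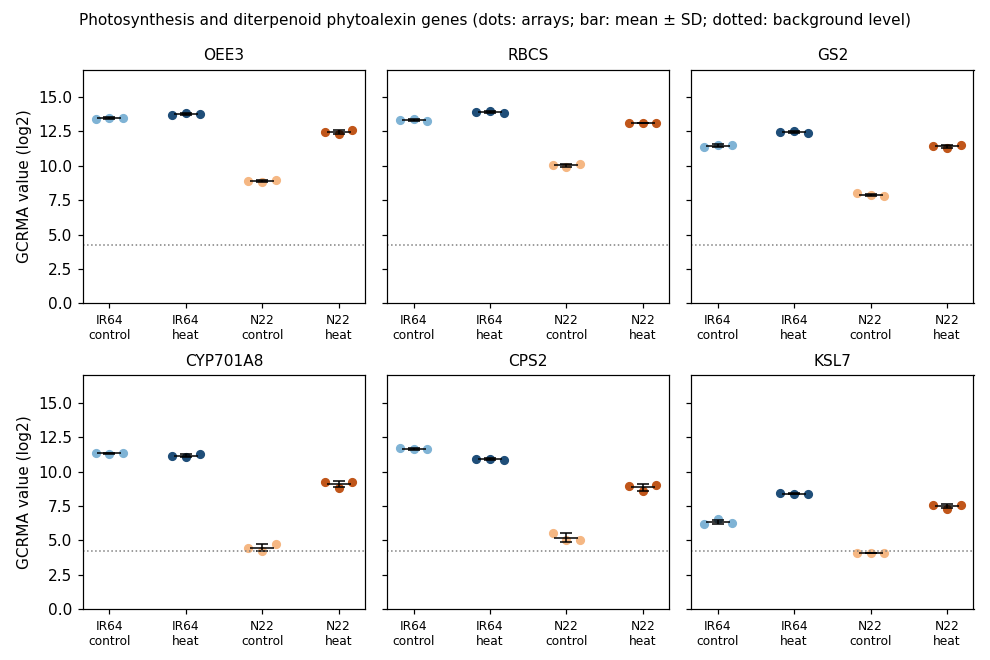
GCRMA values (log2, vertical axis) of 3 photosynthesis genes (OEE3, RBCS, GS2) and 3 diterpenoid phytoalexin genes (CYP701A8, CPS2, KSL7) in the 4 groups, with dots for arrays, bars for mean ± SD (n = 3) and a dotted line at the background level of 4.20. OEE3 had a mean of 8.90 in N22 control and of 12.47 in N22 heat, against 13.48 and 13.75 in IR64 control and heat.

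Water channel, floral and metal genes also rose in N22, and genes of cell division fell. The aquaporin, MADS-box and metal lists were lower in N22 control than in IR64 control (below), and the cell cycle list was higher. Both comparisons share the N22 control arrays. Of 23 aquaporin genes, 12 rose, 1 fell and 10 were not called, with 13 called when adjusted over the list alone (median 0.52, adjusted p = 0.00647, and adjusted p = 0.209 with an estimated correlation), with PIP2-7 (shared probe set) rising by 2.85 ± 0.10. Of 26 MADS-box genes, which include the floral organ identity genes, 15 rose, 4 fell and 7 were not called, with 19 called when adjusted over the list alone (median 0.62, or 0.41 with values raised to background, adjusted p = 0.0249, and adjusted p = 0.374 with an estimated correlation). MADS45 (shared probe set) rose by 2.23 ± 0.13 and MADS58 by 1.36 ± 0.07. Of 47 metal homeostasis genes, 22 rose, 6 fell and 19 were not called (median 0.28, or 0.12 with values raised to background, adjusted p = 0.0203, and adjusted p = 0.261 with an estimated correlation), with ZIP4 rising by 1.69 ± 0.09. Of 86 genes of the cell cycle and DNA replication, 57 fell, 9 rose and 20 were not called, with 69 called when adjusted over the list alone (median -0.61, adjusted p = 1.3e-05, and adjusted p = 0.130 with an estimated correlation). The cyclin gene CYCB2 fell by 1.88 ± 0.10 and the kinesin gene KIN10B by 1.83 ± 0.08. Mitochondrial respiration genes (15 down, 2 up, 6 not called, and 19 called when adjusted over the list alone) and proteasome subunit genes (15 down, 1 up, 3 not called, and 16 called when adjusted over the list alone) fell in N22 as well. Their medians were -0.37 and -0.43, at adjusted p = 0.00862 and 0.00542, and at adjusted p = 0.126 and 0.231 with an estimated correlation. The porin gene VDAC5 fell by 1.47 ± 0.06 and PAB1 by 0.87 ± 0.07, while the alternative oxidase gene AOX1 rose at least 1.43-fold.

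Other named rises in N22 were those of BURP16 (LOC4348595), at least 34.7-fold, BGLU12 (LOC4336145), at least 6.62-fold, BHLH172, at least 6.44-fold, and GLT2, 4.50 ± 0.14. The falls were smaller. RA17 (LOC4342722), a seed allergen gene, fell by 2.38 ± 0.12, TF1 (LOC4325864, shared probe set) by 2.40 ± 0.11, ORC1 (LOC4340349), of the origin recognition complex, by 2.39 ± 0.13. DPE1 (LOC4343975), which acts on starch breakdown products, changed by -2.29 ± 0.13. The peptide hormone precursor gene PSK4 (LOC4342304) fell by 2.24 ± 0.08 and the metal transporter gene Nramp1 (LOC4342862) by 2.21 ± 0.09. The cystatin gene OC-VI (LOC4332021), the phosphatase gene OsPP2C16 (LOC107276004), YAB5 (LOC4336518) and the hexokinase gene HXK3 (LOC4326516) fell to background, at least 2.90-fold, 2.80-fold, 2.07-fold and 2.05-fold. Of the 19 sentinel genes, 8 rose, 2 fell and 9 were not called, with 10 called when adjusted over the list alone. HSP26.7 rose by 4.08 ± 0.34, HSFB2C by 1.87 ± 0.11 and HSP101 by 1.23 ± 0.08, and the list was not called (median 0.26, or 0.00 with values raised to background, adjusted p = 0.182).

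In total, limma called 15412 of 29801 probe sets for heat in N22, 7121 up and 8291 down, of which 5084 moved at least 2-fold (3270 up, 1814 down). With median centring the median of all probe sets was -0.20 in place of -0.01, with 5563 up and 13431 down (at least 2-fold, 2655 up and 2894 down), so this scaling ends the excess of 2-fold rises, which quantile normalization keeps (2942 up, 2184 down). The 3' minus 5' difference of GAPDH was 8.59 ± 0.14 in N22 control and 8.81 ± 0.17 in N22 heat (SD, n = 3; exact permutation p = 0.2). The probe sets for 5.8S, 28S and 25S ribosomal RNA moved by 3.07, 1.76 and 1.16 with heat in N22 (exact permutation p = 0.1 each, the smallest possible), along with the gene groups described for heat in N22. The 18S probe sets changed by -0.06 and 0.01 (exact permutation p = 0.7 and 0.9).

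**Figure D4:**
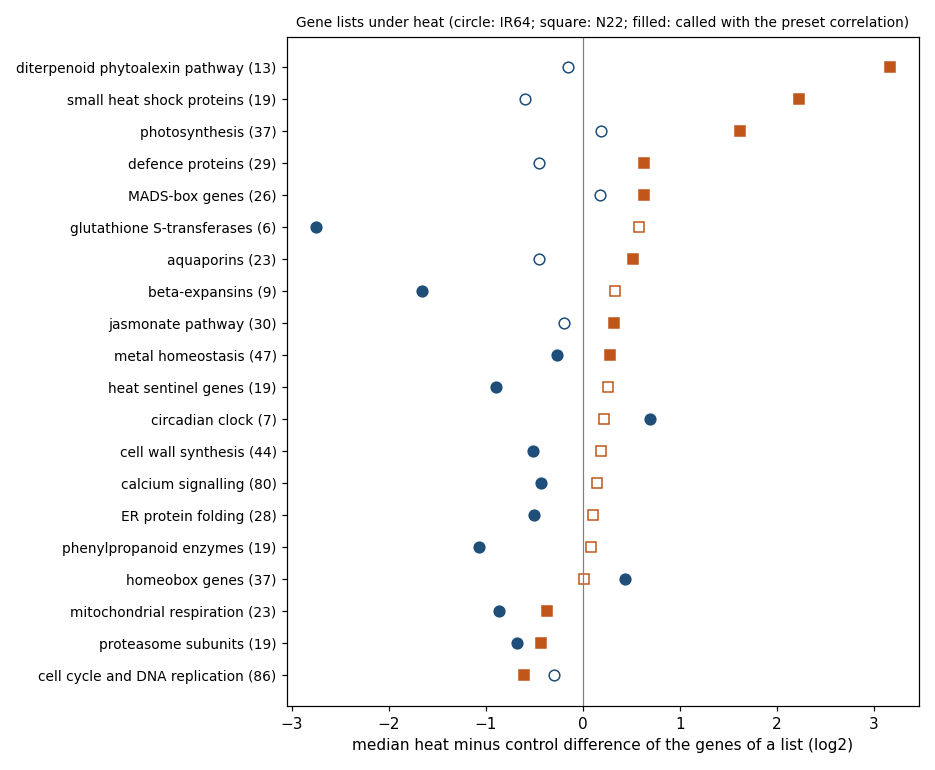
Median heat minus control difference (log2, horizontal axis) of the genes of each list called for heat in IR64 or N22, with circles for IR64, squares for N22, filled symbols for calls with the preset correlation and the number of genes in brackets. Small heat shock protein genes had a median of -0.60 in IR64 and 2.22 in N22.

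The heat responses of the cultivars were compared by the test of the difference, in which small heat shock proteins had the largest median among the called lists. Among small heat shock protein genes, 16 of 19 had a more positive heat effect in N22, 2 a more negative one and 1 did not pass, with 19 called when adjusted over the list alone (median 4.59, or 4.14 with values raised to background, adjusted p = 1.4e-05, and adjusted p = 0.126 with an estimated correlation). The heat effect of HSP17.4 was higher in N22 by 7.70 ± 0.22 (SE, 3 arrays per group), that of HSP17.7 by 5.33 ± 0.10 and that of HSP17.9B by 5.07 ± 0.08. HSP16.9A went the other way, with a heat effect lower by -2.10 ± 0.09 in N22, where it was already at 12.58 in control. HSP21.9 stayed at background in IR64 in both conditions while it rose in N22.

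Wall and phenylpropanoid genes fell in IR64, while in N22 under heat 20 rose and 4 fell of 44 cell wall synthesis genes, 7 rose and 2 fell of 19 phenylpropanoid genes, and 5 rose and 2 fell of 9 beta-expansin genes. These lists were not called for heat in N22 (adjusted p = 0.117, 0.279 and 0.394). The heat effect was more positive in N22 for 15 of 19 phenylpropanoid genes and more negative for 1, with 3 not called and 16 called when adjusted over the list alone (median 2.03, adjusted p = 0.000217, and adjusted p = 0.110 with an estimated correlation), among them 4CL3 by 6.01 ± 0.12. For cell wall synthesis the numbers were 32, 4 and 8 of 44 (median 1.07, adjusted p = 0.000279, and adjusted p = 0.126 with an estimated correlation), with CESA4 at 5.75 ± 0.13 and BC1 at 6.49 ± 0.18. For beta-expansins they were 7, 1 and 1 of 9 (median 1.87, adjusted p = 0.0203, and adjusted p = 0.156 with an estimated correlation). EXPB9 differed by 7.76 ± 0.28, and EXPB10 had means of 6.62 and 2.45 in IR64 control and heat and of 2.42 and 6.13 in N22. For glutathione S-transferases they were 5, 0 and 1 of 6, with 6 called when adjusted over the list alone (median 3.49, adjusted p = 0.00226, and adjusted p = 0.153 with an estimated correlation), with GST1 (shared probe set) at 5.71 ± 0.15. Some wall and phenylpropanoid genes were already low in N22 control. There 4CL3 read 4.37 to 4.62 and BC1 4.03 to 4.52, near background, so a fall could hardly be seen. CESA4 read 7.17 to 7.28 in N22 control and 6.98 to 7.14 in N22 heat. For 4CL3 and CESA4 the difference thus rests on the fall in IR64.

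The photosynthesis list differed in the same direction, with 25 genes more positive in N22, 6 more negative and 6 not called, and 31 called when adjusted over the list alone (median 1.24, adjusted p = 0.000213, and adjusted p = 0.261 with an estimated correlation). CHLP, of chlorophyll synthesis, differed by 3.83 ± 0.13. Defence proteins (22, 2 and 5; 25 called when adjusted over the list alone; median 1.39, or 0.84 with values raised to background) and phytoalexin genes (11, 0 and 2; median 2.69) had adjusted p = 0.000491 and 0.000532, and adjusted p = 0.258 and 0.252 with an estimated correlation. The gene of the defence protein PBZ1 differed by 3.90 ± 0.13 and CYP71Z7 by 4.28 ± 0.17. Aquaporins (18, 1 and 4; 19 called when adjusted over the list alone; median 1.23) and calcium signalling (47, 11 and 22; 60 called when adjusted over the list alone; median 0.56) had adjusted p = 0.000532 and 0.00537, and both had adjusted p = 0.126 with an estimated correlation. PIP2-2 (shared probe set) differed by 3.01 ± 0.08 and CIPK14 (shared probe set) by 4.23 ± 0.16. ER folding (18, 4 and 6; 22 called when adjusted over the list alone; median 0.67) and metal homeostasis (26, 5 and 16; median 0.50) had adjusted p = 0.00862 and 0.00564, and adjusted p = 0.153 and 0.236 with an estimated correlation. CRO1 (shared probe set) differed by 3.93 ± 0.09 and MTP3 by 1.94 ± 0.09. Zinc-finger stress proteins (11, 1 and 6 of 18; median 0.52) had adjusted p = 0.0307, and adjusted p = 0.156 with an estimated correlation, with SAP16 at 1.28 ± 0.10. Median centring ended the zinc-finger call (median 0.22, adjusted p = 0.0693).

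The abscisic acid list was the single called list with a more negative heat effect in N22. Of its 73 genes, 32 were more negative, 17 more positive and 24 not called, with 49 called when adjusted over the list alone (median -0.30, adjusted p = 0.0381, and adjusted p = 0.326 with an estimated correlation). The kinase gene SAPK9 (shared probe set) differed by -2.16 ± 0.12 and the phosphatase gene OsPP2C08 by -1.73 ± 0.09. Median centring ended this call (median -0.60, adjusted p = 0.0606), with the median of all probe sets at -0.31. The spike-ins differed in this contrast by -1.04 (added at hybridisation) and -1.36 (added at labelling), both more negative than the median of the abscisic acid list. Other genes with a more negative effect in N22 were CSLA9 (LOC4341571) at -3.17 ± 0.10, the dehydrin gene RAB21 (LOC4350454, shared probe set) at -3.23 ± 0.23 and DPE1 at -2.88 ± 0.19. The argonaute gene AGO14 (LOC4342603) had means of 3.19 and 5.71 in IR64 and 6.79 and 5.69 in N22, OsPP2C31 (LOC4332406) of 2.47 and 4.65 against 9.29 and 8.54, and LEA19 (shared probe set) of 3.77 and 5.76 against 10.22 and 9.32. Of the 19 sentinel genes, 12 had a more positive effect in N22, 3 a more negative one and 4 were not called, with 15 called when adjusted over the list alone (median 1.28, adjusted p = 0.0382, and adjusted p = 0.245 with an estimated correlation). HSFB2C differed by 4.97 ± 0.15, BIP1 by 2.65 ± 0.14 and HSP101 by 2.13 ± 0.11. Without N22 control replicate 1 that call ended (adjusted p = 0.0511).

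In total, limma called 16508 probe sets for the difference of heat effects, 8744 more positive and 7764 more negative in N22, of which 8308 differed at least 2-fold (5129 and 3179). With median centring the median of all probe sets was -0.31 in place of -0.01, with 6594 and 13813 (at least 2-fold, 3832 and 5366), and quantile normalization gave 4362 and 4279 at least 2-fold, so the direction of the excess rests on the scaling. The 3' minus 5' difference of GAPDH moved by 3.15 with heat in IR64 and by 0.23 in N22, so RNA quality shifts along with the difference of heat effects too. N22 panicles also held seed storage transcripts that IR64 panicles lacked in both conditions (below). A difference in tissue was thus not told apart from a difference in heat response, here or for the N22-specific genes. The series asks for heat genes specific to N22. By the count alone, 2011 probe sets were called at 2-fold or more in N22 and not called in IR64, 1021 up and 990 down, and for 1891 of them (960 up, 931 down) the difference was itself called. Among the 20 genes named for heat in N22, 11 met both conditions, among them HSP21.9, HSP18.1, BURP16 and CYP701A8 with rises and OC-VI, RA17, HXK3 and Nramp1 with falls. The conditions also pass genes by their level in IR64. RA17 lay at background in IR64 control, where no fall could be seen. CYP701A8 read 11.28 to 11.35 in IR64 control and 11.08 to 11.28 in IR64 heat, above the 8.82 to 9.23 of N22 heat. With the filter at the 75th percentile of the table, fewer probe sets were tested and the counts were 1124 and 1099.

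Across the 29801 probe sets, which are not independent replicates, the heat effects of the cultivars correlated at Pearson r = 0.150 and Spearman rho = 0.104. At 2-fold or more, 1451 probe sets were called in both cultivars, 1004 in the same direction and 447 in opposite directions. Independent lists of these sizes would give 210 shared rises and 198 shared falls, against 764 and 240 found. The expected counts given here take every tested probe set as able to move in both cultivars. A fall can hardly be seen where a control group lies at background, so 198 is likely too low and 240 is no clear excess. GLT2, BHLH172 and HSP16.9A are among the genes that rose in both. Of those that moved in opposite directions, 387 rose in N22 and fell in IR64 and 60 did the reverse, where 474 in all would be given by independent lists. The totals at 2-fold lean the same way, with 3270 rises and 1814 falls in N22 and 1917 rises and 3254 falls in IR64. Independent lists would thus be uneven in this direction too.

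In the open-field controls, N22 panicles held seed storage transcripts that IR64 panicles lacked. The seed allergen gene RA14 (LOC4342723, shared probe set) was at least 1922-fold higher in N22, with a mean of 15.11 ± 0.06 (SD, n = 3) against background in IR64. The glutelin genes GLUA-3 (LOC4333164) and GLUD-1 (LOC4328877) were at least 1585-fold and 1107-fold higher, and the glutelin genes GLUA-1 (LOC4327027) and GLUB-5 (LOC4328968), on shared probe sets, at least 936-fold and 861-fold. TIP3-1 (LOC4348981, shared probe set), a water channel of the protein storage vacuole, was at least 1450-fold higher, RA17 at least 424-fold and the lipid transfer protein gene LTP-2 (LOC4331362) at least 642-fold. Of 13 storage protein genes, 12 were higher in N22, 1 lower and 0 not called, with 13 called when adjusted over the list alone (median 11.24, or 9.87 with values raised to background, adjusted p = 4.7e-06, and adjusted p = 0.126 with an estimated correlation). Of 12 starch synthesis genes, 9 were higher, 3 lower and 0 not called, with 12 called when adjusted over the list alone (median 3.50, adjusted p = 0.0346, and adjusted p = 0.178 with an estimated correlation). The starch synthase genes ALK and SSI were at least 453-fold higher and higher by 4.77 ± 0.13, and AGPS2 (shared probe set), for ADP-glucose synthesis, by 4.72 ± 0.08 (SE, 3 arrays per group), with SSI and AGPS2 above 14 in N22 control, near saturation. Median centring ended the call of the starch list (adjusted p = 0.0665).

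**Figure D5:**
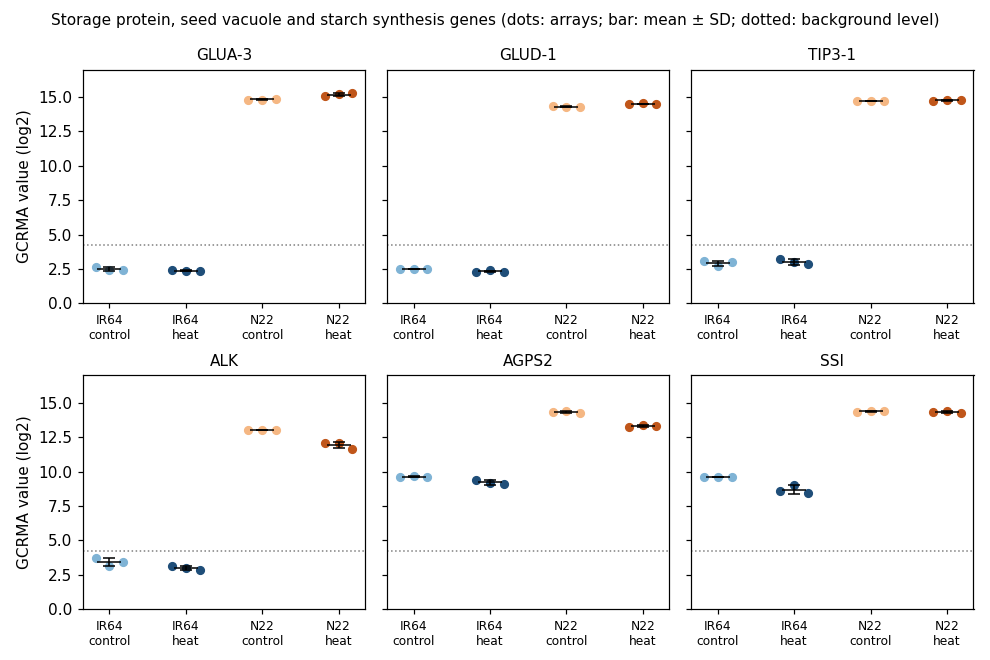
GCRMA values (log2, vertical axis) of 3 storage and seed vacuole genes (GLUA-3, GLUD-1, TIP3-1) and 3 starch synthesis genes (ALK, AGPS2, SSI) in the 4 groups, with dots for arrays, bars for mean ± SD (n = 3) and a dotted line at the background level of 4.20. GLUD-1 had means of 14.32 and 14.52 in N22 control and heat and of 2.50 and 2.33 in IR64 control and heat.

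Lower in N22 controls were genes of lignin, light capture and defence. PAL06 was lower by -7.49 ± 0.21, 4CL3 by -7.49 ± 0.09, BC1 by -7.14 ± 0.13 and HSP17.9B (LOC4325695) by -7.14 ± 0.05, and 4CL5 was at least 117-fold lower. Both 4CL3 and BC1 lay near background in N22 control. The histone gene H2B.10 (LOC4324495) and the flowering regulator MADS56 (LOC4349237) were at least 80.9-fold and 69.4-fold lower. The chitinase gene Cht2 (LOC4349267) differed by -7.26 ± 0.23, though another of its probe sets was called the opposite way. Of 19 phenylpropanoid genes, 15 were lower, 1 higher and 3 not called, with 16 called when adjusted over the list alone (median -2.74, adjusted p = 0.00124, and adjusted p = 0.126 with an estimated correlation). Of 37 photosynthesis genes, 31 were lower, 4 higher and 2 not called, with 35 called when adjusted over the list alone (median -1.93, adjusted p = 4.7e-06, and adjusted p = 0.213 with an estimated correlation), with rca (Rubisco activase, shared probe set) lower by -4.72 ± 0.09. Of 29 defence genes, 22 were lower, 2 higher and 5 not called, with 24 called when adjusted over the list alone (median -1.67, or -1.10 with values raised to background, adjusted p = 0.00128, and adjusted p = 0.267 with an estimated correlation), with PBZ1 lower by -5.68 ± 0.09. Of 13 phytoalexin genes, 11 were lower, 0 higher and 2 not called (median -3.73, or -2.67 with values raised to background, adjusted p = 0.00120, and adjusted p = 0.261 with an estimated correlation). CPS2, which makes their precursor, was lower by -6.47 ± 0.15.

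Lists of transport, redox and signalling genes were also lower in N22 controls. They were metal homeostasis (35 lower, 3 higher, 9 not called, median -1.45), aquaporins (19, 3 and 1, median -2.29), potassium and nitrogen transport (22, 4 and 8, median -1.06, or -0.60 with values raised to background), antioxidant enzymes (18, 3 and 1, median -1.29), glutathione S-transferases (5, 0 and 1, median -3.91), MADS-box genes (19, 3 and 4, median -1.91), cytokinin genes (19, 6 and 3, median -1.37) and flowering time genes (10, 1 and 0, median -1.27). Their adjusted p values were 0.000159, 0.00323, 0.00664, 0.00564, 0.0254, 0.00368, 0.0329 and 0.0381. With an estimated correlation the adjusted p values were 0.126, 0.159, 0.126, 0.252, 0.245, 0.267, 0.420 and 0.252. When adjusted over the list alone, 22 aquaporin, 21 antioxidant, 5 glutathione S-transferase and 22 MADS-box genes were called. ZIP3 was at least 35.9-fold lower, PIP1-1 lower by -4.60 ± 0.08, APX1, an ascorbate peroxidase, by -3.14 ± 0.07, MADS1 by -5.21 ± 0.11 and the response regulator gene RR9 by -4.48 ± 0.10. Higher in N22 were cytosolic ribosomal protein genes (21 higher, 3 lower, 1 not called, median 0.52) and genes of the cell cycle and DNA replication (56, 19 and 11, median 0.79), with 24 and 75 called when adjusted over the list alone. Their adjusted p values were 0.00564 and 0.00226, and 0.217 and 0.245 with an estimated correlation. RPS15 was higher by 1.37 ± 0.06 and CYCD5-2 by 2.79 ± 0.08.

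In total, limma called 21047 of 29801 probe sets between the control groups, 10449 higher and 10598 lower in N22, of which 12423 differed at least 2-fold (5695 higher, 6728 lower). Median centring moved the median of all probe sets by 0.20 and gave 14534 higher and 9119 lower (at least 2-fold, 6838 and 5982). The 3' minus 5' difference of GAPDH was larger in N22 control than in IR64 control by 3.80 (exact permutation p = 0.1, the smallest possible), and this difference goes with every gene group described between the control groups. Ribosomal RNA probe sets differed as well. The means in IR64 control and N22 control were 11.10 and 12.58 for 25S and 11.21 and 12.22 for 28S. For the 18S probe sets they were 10.24 and 10.94, and 10.63 and 11.93.

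Under heat, N22 panicles held more storage transcripts and more small heat shock protein transcripts than IR64 panicles. GLUA-3 was at least 2031-fold higher in N22, RA14 at least 1565-fold, GLUB-5 at least 1279-fold, GLUD-1 at least 1275-fold, GLUA-1 at least 1022-fold and TIP3-1 at least 1517-fold. HSP21.9 was at least 892-fold and HSP26.7 (LOC4332237) at least 492-fold higher. Of 13 storage protein genes, 11 were higher, 1 lower and 1 not called, with 12 called when adjusted over the list alone (median 11.83, or 9.997 with values raised to background, adjusted p = 1.6e-06, and adjusted p = 0.126 with an estimated correlation). Of 19 small heat shock protein genes, 17 were higher, 2 lower and 0 not called, with 19 called when adjusted over the list alone (median 3.29, adjusted p = 2.2e-05, and adjusted p = 0.126 with an estimated correlation), with HSP17.4 higher by 6.92 ± 0.15 (SE, 3 arrays per group).

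ER folding genes (19 higher, 4 lower, 5 not called, median 0.84) and the late embryogenesis genes of 8 members (6, 1 and 1, median 1.87, or 0.99 with values raised to background) were higher in heated N22 than in heated IR64, as were mitochondrial respiration (16, 4 and 3, median 0.45), proteasome (15, 1 and 3, median 0.36), ribosomal protein (20, 3 and 2, median 0.62), cell cycle (48, 14 and 24, median 0.48, or 0.32 with values raised to background) and beta-expansin genes (8, 0 and 1, median 2.04, or 1.13 with values raised to background). Their adjusted p values were 0.00216, 0.0365, 0.0341, 0.0135, 0.00134, 0.00538 and 0.00519, and 0.126, 0.295, 0.156, 0.253, 0.156, 0.261 and 0.126 with an estimated correlation. When adjusted over the list alone, 23, 7, 21, 16, 23 and 64 genes of the first 6 of these lists were called. BIP1 was higher by 3.60 ± 0.10, PDIL1-4 by 6.12 ± 0.10, EM, an embryo gene, at least 135-fold and EXPB3 (shared probe set) by 3.80 ± 0.15. Raising values to background ended the call of the late embryogenesis list (adjusted p = 0.0934), and quantile normalization that of the mitochondrial list (adjusted p = 0.0814).

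Lower in heated N22 panicles were photosynthesis genes (32 lower, 1 higher, 4 not called, median -0.81), MADS-box genes (20, 3 and 3, median -1.18), clock genes (7, 0 and 0, median -1.95), metal homeostasis (32, 7 and 8, median -0.69), potassium and nitrogen transport (22, 3 and 9, median -0.59, or -0.27 with values raised to background), cytokinin genes (18, 4 and 6, median -1.06), homeobox genes (24, 4 and 9, median -0.61) and flowering time genes (9, 1 and 1, median -1.10). Their adjusted p values were 4.05e-05, 0.00244, 0.00335, 0.00438, 0.0203, 0.00529, 0.0241 and 0.0332, and 0.245, 0.261, 0.156, 0.219, 0.156, 0.317, 0.261 and 0.245 with an estimated correlation. When adjusted over the list alone, 33, 23 and 7 genes of the first 3 of these lists were called. The homeobox call ended without a filter (median -0.25, adjusted p = 0.0511) and the flowering time call under median centring (adjusted p = 0.0506). PRR37 was lower by -3.24 ± 0.09, FTSH9 by -1.75 ± 0.06 and RR9 by -3.92 ± 0.10. H2B.10, the lipoxygenase gene LOX9 (LOC4345994), MADS56 and PDX12 (LOC4347937) were at least 52.8-fold, 37.3-fold, 31.9-fold and 16.5-fold lower. BGLU5 (LOC4326948) was lower by -5.04 ± 0.20, DCL2A (LOC4333337, shared probe set), a dicer-like gene, by -4.76 ± 0.09, pinA (LOC9268662) by -6.35 ± 0.54 and Cht2 by -4.63 ± 0.23, again with a probe set called the opposite way.

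In total, limma called 18795 of 29801 probe sets between the heated groups, 8820 higher and 9975 lower in N22, of which 9282 differed at least 2-fold (4677 higher, 4605 lower). With median centring the median of all probe sets was -0.11 in place of -0.01 and the 2-fold split turned to 4241 higher and 5243 lower, and quantile normalization turned it to 4303 and 5196. The 3' minus 5' difference of GAPDH was 7.93 ± 0.16 in IR64 heat and 8.81 ± 0.17 in N22 heat (SD, n = 3), and the 25S and 5.8S ribosomal RNA probe sets had means of 9.77 and 5.74 in IR64 heat and of 13.74 and 8.96 in N22 heat, which goes with every gene group described between the heated groups. The cultivar differences in control and in heat correlated at Pearson r = 0.785 and Spearman rho = 0.718 across probe sets, and of 6827 probe sets called at 2-fold or more in both, 6645 had the same direction. No list was called in any of the 5 contrasts with an estimated correlation, whose smallest adjusted p was 0.110, so every list call rests on the preset correlation of 0.01. The median, mean and test of a list differed in sign in 29 of 260 tests, of which 0 were called.

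Several list medians moved by over 1.5 times under other settings while their calls stayed. Without a filter the median for heat in IR64 was -0.58 for beta-expansins, and for heat in N22 it was 0.17 for MADS-box genes, 0.14 for the jasmonate pathway, 0.17 for aquaporins and 0.08 for metal homeostasis. Between the control groups it was -1.04 for MADS-box genes, between the heated groups -0.37 for potassium and nitrogen transport, and for the difference 0.30 for metal homeostasis. With median centring it was -0.16 for metal homeostasis in IR64 heat, and in N22 heat 0.12 for the jasmonate pathway, 0.32 for aquaporins, 0.08 for metal homeostasis and -0.56 for mitochondrial respiration. For the difference, centring gave 0.37 for ER folding, 0.20 for metal homeostasis and 0.25 for calcium signalling. Quantile normalization gave 0.23 for proteasome subunits between the heated groups and, for the difference, -0.50 for the abscisic acid pathway, 0.34 for zinc-finger stress proteins and 0.31 for metal homeostasis. The mean of a gene's probe sets gave -0.83 for beta-expansins in IR64 heat and -0.36 for homeobox genes between the heated groups. Leaving out N22 heat replicate 1 gave 0.42 for defence proteins in N22 heat. Leaving out IR64 heat replicate 2 gave -0.18 for metal homeostasis in IR64 heat. The filter at the background level, chosen after the data were seen, gave larger medians, such as -2.06 for phenylpropanoid enzymes in IR64 heat.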

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

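The tests of grain tissue, of small heat shock proteins and of photosynthesis genes were chosen after the result was seen, with thresholds set when part of the values was known. The test of probe variants and the splits of the arrays were written before the data were examined.

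The heat effects of the cultivars differed by a test of the difference itself, for 16508 probe sets, 8308 of them at least 2-fold. By list, the median difference of heat effects (N22 minus IR64) was 4.59 for small heat shock proteins, 3.49 for glutathione S-transferases, 2.69 for phytoalexin genes, 2.03 for phenylpropanoid enzymes, 1.87 for beta-expansins and 1.39 for defence proteins. It was 1.28 for heat sentinel genes, 1.24 for photosynthesis, 1.23 for aquaporins, 1.07 for cell wall synthesis, 0.67 for ER folding, 0.56 for calcium signalling, 0.52 for zinc-finger stress proteins, 0.50 for metal homeostasis and -0.30 for the abscisic acid pathway. All 15 calls rest on the preset correlation. Among genes with no group at background, EXPB9 differed by 7.76, HSP17.4 by 7.70, BC1 by 6.49, RAB21 by -3.23, CSLA9 by -3.17 and DPE1 by -2.88. BC1 read 4.03, 4.52 and 4.21 in N22 control, next to background, so its difference is a poor measure of size. In HSP21.9 (11.09), EXPB10 (7.88), 4CL5 (7.18), NifU1 (6.96), BURP16 (6.86), hox14 (-5.03), AGO14 (-3.63), OC-VI (-3.21), OsPP2C31 (-2.93), LEA19 (-2.89) and the sentinel genes HSP26.7 (4.63), HSFA2C (2.03) and HSFB2B (1.02) at least 1 group lay at background, so the fitted differences are no measure of size. Of the other sentinel genes, HSFB2C differed by 4.97, BIP1 by 2.65, APX1 by 2.59, HSFA2D by 2.30, HSP101 by 2.13, HSP81-1 by 1.96, HSFB2A by 1.32, APX2 by 1.28, HSFA1 by 0.44, HSFA2E by -0.40, HSP81-2 by -0.83 and HSP16.9A by -2.10. The HSFA1 call ended with no filter (adjusted p = 0.0625), quantile normalization (0.27, adjusted p = 0.136), median centring (0.13, adjusted p = 0.428), array weights (adjusted p = 0.0602) and without each of several arrays, and the HSFB2B call ended with quantile normalization (adjusted p = 0.0674). The GAPDH 3' minus 5' difference moved by 3.15 with heat in IR64 and by 0.23 in N22, so RNA quality goes with this contrast. N22 panicles may also have held more grain tissue than IR64 panicles in both conditions. The difference of heat effects was not told apart from such a difference in tissue.

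The probe sets for ribosomal RNA and for spike-ins, left out of the tests of genes, carried signals of their own. From control to heat in N22, the probe sets for 5.8S, 28S and 25S ribosomal RNA moved by 3.07, 1.76 and 1.16, and the 18S probe sets by -0.06 and 0.01. In IR64 the spike-ins added at hybridisation moved by 0.82 and those added at labelling by 1.51, against -0.22 and 0.15 in N22.

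Storage genes were higher in N22 than in IR64 in both conditions, and starch genes were called as a list in control alone (in heat, adjusted p = 0.121). If variants under the probes made the cultivar differences, pairs of probe sets of 1 gene would differ in them. Their correlation was 0.654 over 6580 pairs, 1.09 times the 0.601 that heat effects gave over 5615 pairs, which argues against variants as the whole cause. N22 panicles may have held more grain tissue: 5 of 5 other seed genes (VPE1, TIP3-1, TIP3-2, VP1 and PDIL1-1) were at least 2-fold higher in N22 in both conditions. TIP3-1 was already among the largest cultivar differences named above, so its outcome was known. Of all 29801 tested probe sets, 5695 were called at least 2-fold higher in N22 in control and 4677 in heat. A difference of the cultivars in seed gene expression at 1 stage was not tested, and VPE1 and PDIL1-1 lay well above background in IR64 as well.

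The rise of small heat shock protein genes in N22 was weighed against RNA quality, normalization and tissue shares. The GAPDH 3' minus 5' difference moved by 0.23 in N22, which argues against a change in 3' excess. Of the ribosomal RNA probe sets 3 moved in N22 (5.8S by 3.07) and those of 18S stayed, and what this shift does to other genes was not tested. The median change of the list exceeded that of the hybridisation spike-ins by 2.44, which argues against the authors' normalization. A changed share of tissues stays open: 61.1% of the genes that rose, 11 of 18, exceeded the other 3 group means by 1 or more, but a tissue with a larger share in N22 heat than in any other group would give this too. A response of N22 to heat also stays open, untested apart from this and from the growing site.

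Photosynthesis genes rose in N22 under heat, with a median of 1.62. The 26 that rose were lower in N22 control than in IR64 control, as were 31 of all 37, but both comparisons share the N22 control arrays. Over the 29801 tested probe sets the N22 heat arrays correlated with IR64 control and heat at a median r of 0.845 and 0.862, and the N22 control arrays at 0.793 and 0.796. Mixing of IR64 RNA into the N22 heat samples would bring up genes that only IR64 expresses, but 84.6% of 39 such probe sets stayed at background in N22 heat. In the reverse direction 94.2% of 155 stayed at background in IR64 heat. A smaller share of grain in the heated N22 panicles remains open. The storage list had a median change of -0.0527 in N22, but 7 of its 13 genes lay above 14, near saturation. Seed genes with means below 14 were mixed. From control to heat in N22, VP1 went from 9.997 to 8.977 and TIP3-2 from 9.21 to 8.92. VPE1 went the other way, from 11.51 to 11.71. Of 12 starch synthesis genes, 7 fell, 2 rose and 3 were not called in N22, with a median of -0.79. The starch list was not called for heat in N22 (adjusted p = 0.117). A response of leaf-like tissue to heat was not tested apart from mixing of RNA and a smaller share of grain.

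Splits of the same arrays into other groups were run to see how much the calls owe to the grouping. A split that parts a group puts the differences between groups into the spread, so few probe set calls were bound to result. Low counts of probe sets in such splits thus lend no weight to the real counts. With 3 against 3 arrays there are 10 splits, too few for a share under 0.05, and 1 of 10 reached the real count of probe sets in each contrast, which is the real split. The real counts and the highest others were 15427 and 2 for heat in IR64, 15412 and 2 for heat in N22, 21047 and 0 for the cultivars in control, and 18795 and 0 in heat. The lists were less tied to the grouping: the real counts and the highest others were 12 and 7, 11 and 11, 16 and 15, and 17 and 15, with 2 of 10 splits reaching the real count for heat in N22. In 3 of these 4 contrasts the highest scrambled split thus gives as many or nearly as many list calls as the real groups, while for heat in IR64 it gives 7 against 12. For the difference, 2 of 100 splits reached 16508. The higher one, with 17075, kept all groups together and swapped heat and control in 1 cultivar, and the highest among splits that part a group was 6879. For lists of the difference, 1 of 100 splits reached 15, with 14 as the highest other. The count of N22-specific probe sets, 1891, was reached in 15 of 100 splits, up to 3769. All 15 kept the N22 groups together, and the highest among the 85 that part them was 1, so this count also depends on how few calls the scrambled IR64 arrays give.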

How the results depend on the processing

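Every total of called probe sets stayed within 1.5 times its value under every alternative except the N22-specific counts, which were 1099 with the difference tested and 1124 without under the filter at the 75th percentile, where fewer probe sets were tested. By direction, median centring moved the falls in N22 from 8291 to 13431 (at least 2-fold, from 1814 to 2894) and the more negative differences from 7764 to 13813 (from 3179 to 5366), since it shifts all values of an array. The correlation of the heat effects of the cultivars, 0.150, was 0.145 with no filter and 0.175 with the 75th percentile filter, and 0.160 and 0.163 with the filter and the raise at background chosen after the data were seen; the cause was not tested. Of 71 list calls, 0 remained with an estimated correlation, while 66 to 71 remained under the other settings and 845 of 852 when an array was left out. Of 425 named values, 416 or more kept their side of the threshold and direction under each setting run on all of them, as did 3051 of 3066 when an array was left out. The cultivar difference of HSFB2A in control turned from -0.20 to 0.00385 under median centring (adjusted p = 0.964), which shifts this contrast by 0.20. Lists were not tested with the 75th percentile filter, other moderation or array weights. Replicates share only a number: of 18 same-number pairs, 1 correlated above 0.1 (r from -0.0535 to 0.104), and 7 of 12 arrays correlated best with their own number. With the number as a block, 15262, 15144, 20910, 18593 and 16278 probe sets were called in the 5 contrasts, 1873 were N22-specific, and 70 of 71 list calls remained, all but metal homeostasis for heat in IR64 (adjusted p = 0.0558). Signal limits the reach of the arrays, since 38.6% of values sit at the floor and genes at background have bounds alone.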

Other observations

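None of the tests in this part was chosen to explain a result. Of the 52 lists tested, 22 were called in no contrast, and the smallest adjusted p among them was 0.0593. Heat stress transcription factor genes were split under heat, with 3 up, 8 down and 8 not called in IR64 (adjusted p = 0.349) and 6 up, 3 down and 10 not called in N22 (adjusted p = 0.490). Meiosis genes had 6 up, 1 down and 7 not called in IR64 (adjusted p = 0.321) and 3, 5 and 6 in N22 (adjusted p = 0.663). Tapetum and exine genes had 2 up, 4 down and 6 not called in IR64 (adjusted p = 0.932) and 2, 5 and 5 in N22 (adjusted p = 0.508). The others were sucrose and hexose metabolism, alpha-expansins, auxin, gibberellin, brassinosteroid, phosphate, senescence, cystatins and autophagy, beta-glucosidases, HSP100 and Clp chaperones, DnaJ co-chaperones, AP2/ERF, NAC and WRKY factors, histones, splicing factors, wax and lipid transfer, glutaredoxins and U-box ligases. HSFA2B had no kept probe set, with all its values next to the floor. A larger response of 1 cultivar had been set down for testing before the data were examined, but the counts for heat were 15427 in IR64 and 15412 in N22, so there was no such pattern to test.

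Some members of the lists do other work than the title says. The storage list holds GLB1, which was higher in IR64, and the inhibitor gene RBTI, and the photosynthesis list holds GS2, CHLP, PORA and FTSH genes. TIP3-1 and TIP3-2 also count among the aquaporins and PDIL1-1 in ER folding, so these lists share genes with the seed group. The 25S ribosomal RNA probe set moved by -1.33 in IR64.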
